A study of Homo sapiens with 12 samples.

How the data were processed

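Total RNA of SCC-25 cells was sequenced from 12 libraries in 4 groups of 3, PA and untreated at 4 days and at 14 days. Per the labels, libraries were made with a stranded kit after ribosomal RNA removal and read as 125-base single reads on a HiSeq2500. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with TopHat2 2.1.1 to hg19, counted per gene with featureCounts 1.6.0 and compared with DESeq2 1.26.0. The deposited values are the authors' count per gene and library, unnormalized whole numbers. The strand setting of the counting and the annotation release were not given in the sources used here, so pseudogenes and genes that overlap or run antisense to another gene are uncertain throughout.

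The deposited table held 57905 genes, all 12 columns were used, and 51996 gene identifiers were found in a gene name table, 39538 of them with a symbol. Names came from that table. Gene types, transcript lengths and GC content came from GENCODE release v29, which rests on a later genome build than the authors' and was used for nothing else. Genes with low counts were removed with edgeR's filterByExpr over the 4 groups, leaving 21529 genes, of which 18088 had a symbol and 20704 (96.2%) a length and GC content. The genes left out held 0.0201% to 0.0349% of the counts of a library. With 74154010 to 101426448 counts per library, a count of 0 leaves room for 3 counts at 95% confidence, which is 0.0296 to 0.0405 CPM. Such floors cover counting error only. SDs and standard errors in the text describe the spread between 3 libraries.

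Counts were scaled with TMM factors and fitted with the edgeR quasi-likelihood method (robust, edgeR 4.0.16, limma 3.58.1, R 4.3.3), with one mean per group over the 12 libraries, 8 residual degrees of freedom and a common dispersion of 0.00852. The contrasts were PA against untreated at 4 days, the same at 14 days, the difference between these contrasts, and untreated at 14 days against untreated at 4 days. Adjusted p-values followed Benjamini and Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. Counts adjusted over the list alone repeated the adjustment within a list. Shared changes were counted among the calls of the first 2 contrasts and compared with independent lists by Fisher's exact test.

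Gene lists of pathways and cell types, with 796 entries of which 756 matched the gene names, were fixed before the data were examined, as were the comparisons, the rule for naming genes and most alternatives. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Each test was repeated with a correlation estimated from the data and with the rotation test fry. Further groups of genes chosen after their values were seen appear only in the closing section.

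Genes were named by a fixed rule. For each PA comparison and for the difference, it took the 10 largest rises and the 10 largest falls among called genes with a symbol and a mean log2 CPM of at least 1, for the PA comparisons also with fully separated groups. It added up to 4 called members of each list with the smallest p, and the genes CPT1A, PDK4, ANGPTL4, PLIN2, CD36, SCD, HMGCS1, GAL, EGR2 and SETD1A whatever their values. For the untreated comparison it took 5 genes in each direction.

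The alternatives were DESeq2 size factors within edgeR, a DESeq2 Wald test (DESeq2 1.42.0), no low-count filter, only the libraries compared, a block for replicate number, a test against 1.2-fold (glmTreat), and leaving out each library in turn. Library totals as the only scaling and the removal of each library's trend with GC content and length (splines with 5 degrees of freedom) were added after the data had been seen, as was leaving out libraries for the lists. Other splits of the libraries into groups were fitted with the same method. Splits of the 6 libraries of a comparison used those libraries alone, so their real counts differ from the main calls. Splits of the day labels used all 12 libraries. The procedure was tested on simulated data with 200 changed genes, 50 for each fold. At 4-fold, edgeR recovered 94%, 100% and 92% of them for the contrasts at 4 days, at 14 days and for their difference, at 2-fold 90%, 90% and 70%, at 1.5-fold 70%, 50% and 30%, and at 1.2-fold 0%, 8% and 2%. The share of false calls was 4.05%, 8.05% and 4.59% with edgeR and 15.1%, 15.7% and 8.8% with DESeq2, and 0 of 29 unchanged lists were called. The interferon list, shifted as well, was called for each contrast. Simulated genes were drawn independently of each other, so the list result says nothing on lists whose members vary together. Far fewer genes were changed than were called in the data, so these rates need not carry over. Replicates were checked for duplicated libraries, and none were found. Figures were drawn with matplotlib 3.10.9.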

Results

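Gene expression was measured by total RNA sequencing in SCC-25, an established human cell line from a squamous cell carcinoma of the tongue. The 12 libraries formed 4 groups of 3: PA and untreated cells at 4 days, and PA and untreated cells at 14 days. The labels do not expand PA, which from knowledge of the study stands for palmitic acid, the saturated fatty acid. They call the groups post-PA, and the titles of treated libraries carry a 4 at both times, but when PA was given and when it was withdrawn is not stated. These groups are called PA here for short, and only the titles at 4 days carry a word for unsorted cells. Total counts were 95375085, 84811638 and 84473872 in the PA libraries at 4 days and 76199878, 88511375 and 99421117 in the untreated ones. At 14 days they were 93215569, 98904946 and 86249796 with PA and 92618218, 101426448 and 74154010 without. No statement says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

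The first principal component of the 21529 tested genes held 51.7% of the variance and the second 21.2%, and replicates of one group differed by more than sampling noise (chi-square per degree of freedom 5.5 to 89.5). PA replicate 3 at 4 days and untreated replicate 2 at 14 days stood apart from the other libraries of their groups. The counts of mitochondrially encoded genes made up 7.3% ± 0.13 (SD, n = 3) of an untreated library at 4 days and 8.29% ± 1.2 of a PA library at 4 days. At 14 days the share was 8.02% ± 0.2 in untreated and 6.55% ± 0.34 in PA libraries. The 10 most abundant genes took 9.51% ± 1 of the counts in PA libraries at 4 days and 7.83% ± 0.11 in untreated ones, and at 14 days 7.16% ± 0.28 in PA and 8.36% ± 0.21 in untreated libraries.

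The comparison at 4 days asked which transcripts differed between PA and untreated cells at the early time. Genes of fatty acid handling, interferon-induced genes and genes of keratinocyte differentiation were higher in PA cells, and genes of mitosis, DNA replication and the mesenchymal state were lower. With an estimated correlation, the fatty acid and interferon lists kept their calls (adjusted p = 0.0392 and 0.0478), while squamous differentiation (0.0907), mitosis (0.101), DNA replication (0.646) and mesenchymal transition (0.103) did not. CD36 (ENSG00000135218), a fatty acid transporter and scavenger receptor, rose 59.9-fold, from 0.627 ± 0.0685 to 37.9 ± 5.24 CPM (SD, n = 3). GPNMB (ENSG00000136235), a glycoprotein of melanosomes and lysosomes, rose from 10.1 ± 0.483 to 353 ± 24.6 CPM, and CXCL14, an epithelial chemokine, rose 34-fold. The long intergenic transcripts LINC00707 and SFTA1P showed the steepest falls among the genes chosen by the naming rule, 27.9-fold and 17-fold.

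Of the 21529 genes tested, 5548 were higher and 5614 lower in PA libraries at 4 days (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 51.8% of all genes. Changes of at least 2-fold were found among 1694 of the higher and 988 of the lower genes. All libraries of one group lay above all of the other for 59.7% of genes, where chance gives 10%. Between the untreated groups at 14 and 4 days that share was 20.1%. Besides CD36, GPNMB and CXCL14, strong rises were those of CMPK2 (log2 fold change 3.6), TRIM22 (3.59), RTP4 (3.58) and IFI44L (3.50), all induced by interferons. They were joined by the suprabasal keratin KRT10 (3.56) and the divergent transcript KLHDC7B-DT (3.44). After the 2 intergenic transcripts, the falls were led by PHACTR3 (−3.39), TMEM156 (−3.39), SMOC1 (−3.27), and the pseudogene RPSAP52 (−3.14). Next came aldehyde oxidase AOX1 (−2.95), the cornified envelope protein sciellin, SCEL (−2.83), SFXN2 (−2.75) and uridine phosphorylase UPP1 (−2.66).

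All 32 tested interferon response genes rose at 4 days, with a median log2 fold change of 2.34 (camera, adjusted p = 2.97e-46, and adjusted p = 0.0478 with an estimated correlation). IFIT3 rose by 2.86, IFIT2 by 2.81, HERC6 by 2.67 and STAT2, a transcription factor of the interferon signal, by 1.57. Among the PPAR targets and fatty acid oxidation genes, 17 of 23 rose and 1 fell, with a median of 0.694 (adjusted p = 3.66e-20, and 0.0392 with an estimated correlation). CPT1A, which brings fatty acids into mitochondria, rose from 44.0 ± 2.58 to 168 ± 4.91 CPM. The acyl-CoA synthetase ACSL1 rose by 1.69, the acyl-CoA dehydrogenase ACADVL by 1.72 and the lipase inhibitor ANGPTL4 by 3 on the log2 scale. The droplet coat gene PLIN2 rose by 2.97, with 9 to 133 counts per library, and PDK4, with 0 to 5 counts, was not tested. In the list of lipid uptake, droplets and efflux 10 of 22 genes rose and 5 fell (median 0.266, adjusted p = 0.000351, and 0.0467 with an estimated correlation). The risers included MYLIP (2.13), which degrades lipoprotein receptors, the cholesterol exporter ABCA1 (1.90) and VLDLR (1.75).

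Squamous differentiation genes were higher for 15 and lower for 5 of 28 (median 0.508, adjusted p = 0.000552, and 0.0907 with an estimated correlation). Besides KRT10, DSG1 rose by 3.23, NOTCH3 by 3.23 and the desmosomal cadherin DSC2 by 1.22. Epithelial adhesion and junction genes were higher for 12 and lower for 2 of 19 (median 0.469, adjusted p = 0.000701, and 0.358 with an estimated correlation). ST14, a membrane protease, stood at 1.10, DSC3 at 0.97 and the desmosomal plakophilin PKP1 at 0.75. Of the 35 genes of epithelial-mesenchymal transition, 23 fell and 7 rose (median −0.532, adjusted p = 9.25e-05, and 0.103 with an estimated correlation). The intermediate filament gene VIM fell by 2.58, INHBA by 2.34 and THBS1 by 1.46, while the lysyl oxidase LOXL2 rose by 1.98. Counting that ignores strand would not part VIM from its overlapping antisense gene VIM-AS1, which fell by 2.22.

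All 27 mitosis and G2/M genes fell, with a median of −1.38 (adjusted p = 7.71e-30, and 0.101 with an estimated correlation). Among them were CDC20, an activator of the anaphase-promoting complex, at −1.92, the checkpoint kinase BUB1 at −1.70 and the kinase AURKA at −1.59. DNA replication genes fell for 22 of 25 (median −0.849, adjusted p = 2.32e-05, and 0.646 with an estimated correlation). CDC45 and the helicase subunit MCM7 were both at −1.25. Of 7 genes in the metallothionein list 4 fell (median −0.628, adjusted p = 0.000205, and 0.0901 with an estimated correlation). MT2A (−2.15) and MT1E (−1.41) led them, close relatives whose reads could be split between copies. Without untreated replicate 3 that median was −0.387. Cytosolic ribosomal protein genes fell for 24 and rose for 3 of 45 (median −0.222, adjusted p = 0.0156, and 0.776 with an estimated correlation), RPL7 by 0.67.

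Hypoxia genes were higher for 16 and lower for 2 of 26 (median 0.436, adjusted p = 0.000111, and 0.0901 with an estimated correlation). The vasoactive peptide gene ADM stood at 1.58, the oxygen sensor EGLN3 at 2.05 and the collagen hydroxylase P4HA2 at 1. Extracellular matrix genes were higher for 22 and lower for 10 of 39 (median 0.465, adjusted p = 0.0106, and 0.659 with an estimated correlation). NID1 rose by 1.62, COL6A1 by 1.39 and COL4A5 by 1.39, and FBN2 fell by 1.55. Of the fixed genes not named so far, the neuropeptide gene GAL fell by 1.75 and EGR2, an early response transcription factor, rose by 1.61. SETD1A, a histone H3 lysine 4 methyltransferase, had a log2 fold change of 0.16 (adjusted p = 0.0578), which turned to −0.16 with the GC and length trend removed (0.0198, with values from 0.011 to 0.921 over the settings). The sterol synthesis gene HMGCS1 was lower, at −0.64 (adjusted p = 0.0174). Its call was lost without PA replicate 3 (0.0559) and without untreated replicate 3 (0.072), and in the test against 1.2-fold (0.0566). Its adjusted p ran from 1.09e-14 to 0.072 over the alternative settings. The desaturase gene SCD was lower, at −0.23 (adjusted p = 0.0338), from 0.00782 to 0.598 over the settings. That call was lost without PA replicate 3 (0.102), untreated replicate 1 (0.0735) or untreated replicate 3 (0.101), and in the test against 1.2-fold (0.598).

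The other lists did not pass the test at 4 days, although single members did. They were immediate early genes (15 higher, 9 lower of 24, adjusted p = 0.0767), nuclear genes of oxidative phosphorylation (2 and 15 of 32, 0.092) and NF-kB and inflammatory cytokines (4 and 10 of 23, 0.165). Among them were also basal keratinocyte genes (10 and 5 of 18, 0.174) and replication-dependent histones (3 and 0 of 8, 0.174). The ATF4 integrated stress response (7 and 2 of 27, 0.23), p53 targets (6 and 3 of 20, 0.23), glycolysis (2 and 7 of 19, 0.252) and the unfolded protein response (3 and 7 of 22, 0.313) did not pass either. The same held for fatty acid synthesis (8 and 11 of 24, 0.379), the NRF2 response (5 and 13 of 25, 0.379) and cholesterol synthesis (6 and 10 of 24, 0.556). The last were H3K4 methylation machinery (5 and 7 of 19, 0.857), neurotrophins and axon guidance (11 and 11 of 35, 0.857) and mitochondrially encoded genes (1 and 0 of 13, 0.906). Markers of fibroblasts (4 and 0 of 8, 0.165), blood cells (2 and 1 of 5, 0.379) and Schwann cells and neurons (2 and 2 of 5, 0.379) were not called. With fry 10 of these lists passed at 4 days. Those higher were histones (2.27e-05), p53 targets (0.000122), blood (0.000201), fibroblast (0.000271) and Schwann cell (0.000502) markers, basal (0.00105) and immediate early genes (0.00551), and those lower oxidative phosphorylation (0.0276), fatty acid synthesis (0.0299) and NF-kB (0.0309). Immediate early genes also passed without PA replicate 2 (0.00942, from 0.00942 to 0.277 over the settings at the preset correlation). Oxidative phosphorylation genes also passed without PA replicate 1 (0.045) or 2 (0.0312, from 0.0312 to 0.274). With 4 endothelial markers, of which 1 fell, that list was too short to test. Median, mean and test differed in sign for the blood, neurotrophin, p53 and Schwann cell lists. Adjusted over the list alone, 14 adhesion genes and 16 squamous genes were higher and 24 genes of epithelial-mesenchymal transition were lower. The counts of the other called lists at 4 days were as over all genes.

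Of the 12 lists called at 4 days, the interferon, PPAR and lipid uptake lists kept the call with an estimated correlation. The lipid uptake list shares CD36 and PLIN2 with the PPAR list, so these calls are not fully separate results. The extracellular matrix call was lost with the GC and length trend removed (adjusted p = 0.185) and without untreated replicate 3 (0.0538), from 0.00205 to 0.185 over the settings at the preset correlation. The ribosomal call was lost with that trend removed (0.0834) and without PA replicate 3 (0.0986, median −0.141), from 0.00175 to 0.0986 over the settings at the preset correlation.

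**Figure D1:**
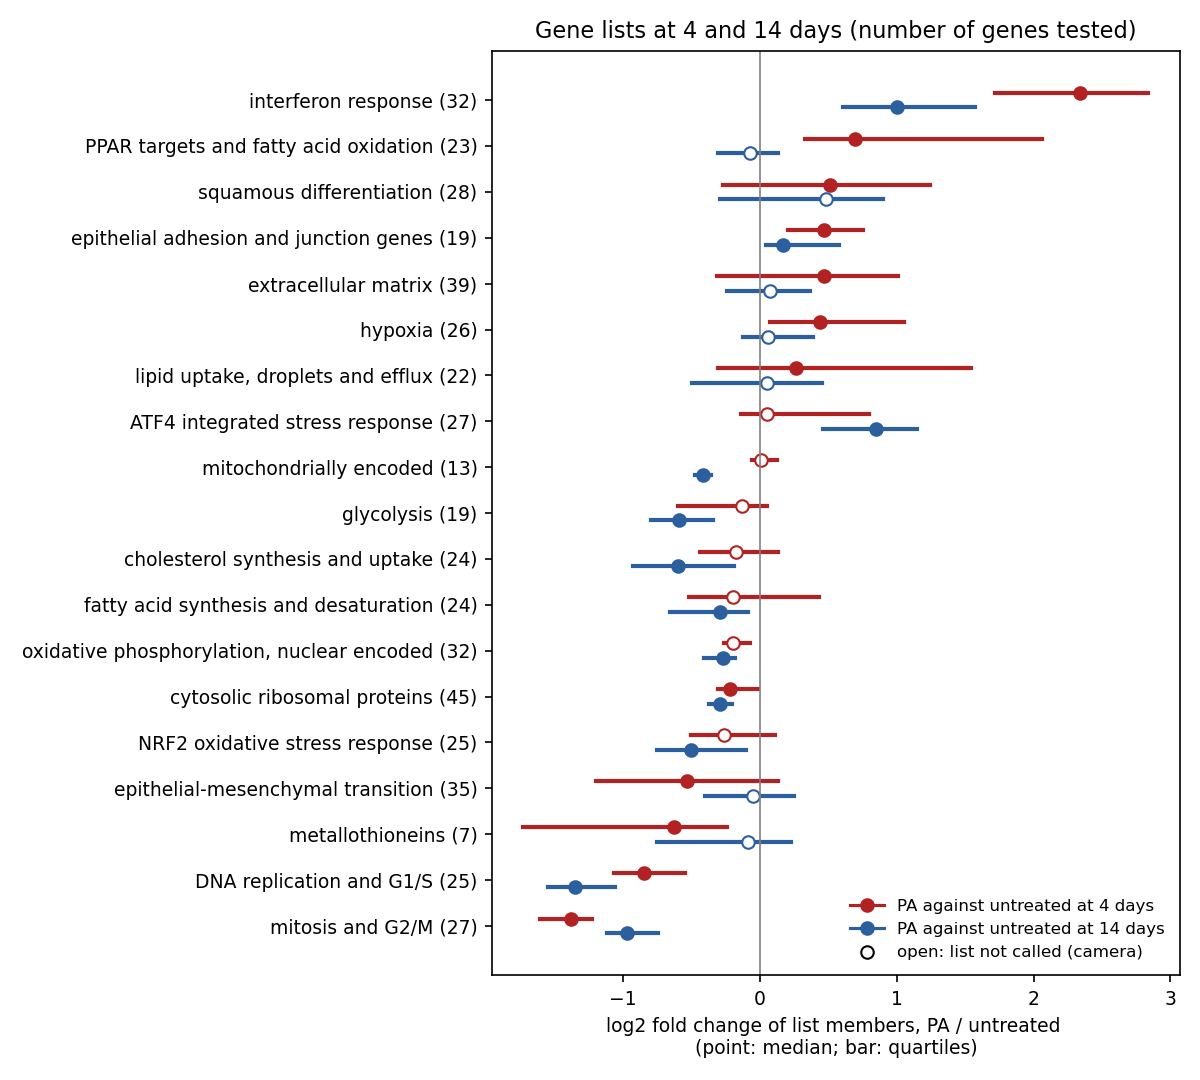
The 19 lists called by camera at 4 or at 14 days, with the log2 fold change of PA over untreated on the horizontal axis, the median of the tested members as a point and their quartiles as a bar (red, 4 days; blue, 14 days; open points, list not called; tested members in brackets). The interferon list had medians of 2.34 and 1.0, the PPAR and fatty acid oxidation list 0.694 and −0.0763, and the DNA replication list −0.849 and −1.35.

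The comparison at 14 days asked which differences between PA and untreated cells were seen at the later time, the comparison that the series names in its design. Genes of DNA replication, mitosis, sterol and fatty acid synthesis, glycolysis and ribosomes were lower in PA cells, and interferon-induced genes were higher. None of these lists kept its call with an estimated correlation (adjusted p from 0.34 to 0.563). KLHDC7B, a kelch repeat gene, rose 13.1-fold, from 0.578 ± 0.489 to 7.40 ± 0.547 CPM (SD, n = 3), and its divergent neighbour KLHDC7B-DT 10.2-fold. GPNMB rose from 9.83 ± 1.45 to 70.9 ± 9.08 CPM and the complement protease C1S from 6.28 ± 2.14 to 44.6 ± 4.99 CPM. The kinase gene CAMK2B fell 7.85-fold, from 10.3 ± 2.25 to 1.31 ± 0.0502 CPM, and KRT19, a keratin of simple epithelia, from 198 ± 76.6 to 41.3 ± 4.38 CPM. CAMK2B was also called higher in untreated cells at 14 than at 4 days, a call that did not hold in all settings.

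In all, 5187 genes were higher and 5577 lower in PA libraries at 14 days, 50% of those tested, with changes of at least 2-fold for 1291 and 724. Groups were fully separated for 60.5% of genes, against 10% by chance and 20.1% between the untreated groups of the 2 times. The split depended on the scaling: with library totals alone 7234 genes were higher and 4004 lower, 64.4% higher against 48.2%. The median of all genes then lay at 0.141 on the log2 scale, so changes at 14 days are relative to that shift. The TMM factor was 1.05 ± 0.016 in PA and 0.968 ± 0.0075 in untreated libraries at 14 days. Further strong rises were those of the interferon-induced XAF1 (2.77) and IFI44L (2.50), CXCL14 (2.72), PNLIPRP3 (2.63), LINC01355 (2.42) and ODF3B (2.30). Further falls were those of PLS1 (−2.85), the peptidylarginine deiminase PADI3 (−2.85), FAM111B (−2.50), TNFRSF8 (−2.35), TM4SF1 (−2.24), N-cadherin CDH2 (−2.14), DPYSL3 (−2.11) and DISP3 (−2.10).

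All 25 DNA replication genes fell at 14 days, with a median of −1.35 (adjusted p = 6.26e-21, and 0.34 with an estimated correlation), MCM5 by 1.52, MCM2 by 1.47 and MCM7 by 1.44. All 27 mitosis genes fell, with a median of −0.973 (adjusted p = 7.81e-26, and 0.34 with an estimated correlation), the kinase PLK1 by 1.45 and CDC20 by 1.10. In the interferon list 27 of 32 genes rose and none fell (median 1.0, adjusted p = 6.51e-17, and 0.34 with an estimated correlation). The RNA sensor IFIH1 stood at 1.17, HERC6 at 1.07, IFIT1 at 1.05 and STAT2 at 0.62.

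Cholesterol synthesis and uptake genes fell for 19 of 24 (median −0.602, adjusted p = 2.92e-09, and 0.365 with an estimated correlation). MVD and MVK were both at −1.05, FDFT1 at −1 and HMGCS1, among the first enzymes of the pathway, at −1.33. Glycolysis genes were lower for 15 and higher for 1 of 19 (median −0.592, adjusted p = 2.14e-07, and 0.34 with an estimated correlation). ENO1 stood at −1.18, PFKP at −0.95 and GAPDH at −0.72. Fatty acid synthesis and desaturation genes were lower for 14 and higher for 4 of 24 (median −0.295, adjusted p = 0.00093, and 0.34 with an estimated correlation). The desaturases FADS2 and FADS1 fell by 1.17 and 1.09 and fatty acid synthase FASN by 1.11. SCD was lower, at −0.30 (adjusted p = 0.0101, from 0.00158 to 0.327 over the settings), a call lost without untreated replicate 2 (0.0528) and in the test against 1.2-fold. NRF2 response genes were lower for 15 and higher for 3 of 25 (median −0.508, adjusted p = 0.000609, and 0.386 with an estimated correlation). NQO1 stood at −1.14 and the transketolase TKT at −0.85.

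Cytosolic ribosomal protein genes fell for 37 of 45 (median −0.294, adjusted p = 9.44e-07, and 0.563 with an estimated correlation), RPS20 by 0.66. Nuclear genes of oxidative phosphorylation were lower for 22 and higher for 1 of 32 (median −0.27, adjusted p = 0.00013, and 0.563 with an estimated correlation), SDHB at −0.52. Mitochondrially encoded genes fell for 11 of 13 (median −0.42, adjusted p = 0.00282, and 0.6 with an estimated correlation), MT-ND6 by 0.58. With library totals alone the medians were −0.17 for ribosomal, −0.147 for oxidative phosphorylation and −0.171 for fatty acid synthesis genes, all of the same sign. ATF4 stress response genes were higher for 15 and lower for 1 of 27 (median 0.848, adjusted p = 3.97e-05, and 0.563 with an estimated correlation), with DDIT3 at 0.85. Untreated replicate 2 at 14 days carried much of that size: without it the median was 0.397, with 17 higher and 2 lower. Adhesion genes were higher for 10 and lower for 2 of 19 (median 0.17, adjusted p = 0.0453, and 0.563 with an estimated correlation), the desmosomal DSG3 at 1.35 and CLDN4 at −0.81. With library totals alone that median was 0.293.

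The PPAR and fatty acid oxidation list was not called at 14 days (2 higher, 7 lower of 23, median −0.0763, adjusted p = 0.363). CD36 was still higher, 3.34-fold, whereas ETFB and ACAA2, enzymes of fatty acid oxidation, both fell by 1.16. CPT1A stood at 46.0 ± 1.73 CPM in untreated and 43.7 ± 1.97 CPM in PA libraries (log2 fold change −0.08, adjusted p = 0.298), ANGPTL4 at −0.20 (adjusted p = 0.308) and PLIN2 at 0.45 (adjusted p = 0.186). GAL was lower, at −0.45 (adjusted p = 0.00465, from 7.8e-05 to 0.066 over the settings), so its call did not hold in all of them. EGR2 was higher by 0.78 and SETD1A higher by 0.20 (adjusted p = 0.0232, from 0.00713 to 0.802 over the settings). The SETD1A call was lost without PA replicate 1 (0.0556), PA replicate 3 (0.0985) or untreated replicate 2 (0.0654) and in the test against 1.2-fold. The unfolded protein response (10 and 3 of 22, adjusted p = 0.0824), squamous differentiation (11 and 6 of 28, 0.114), neurotrophins and axon guidance (4 and 17 of 35, 0.114) and epithelial-mesenchymal transition (7 and 9 of 35, 0.14) did not pass. The unfolded protein response passed with library totals alone (0.0326) and without untreated replicate 1 (0.0225) or 3 (0.0379), from 0.0225 to 0.195 over the settings at the preset correlation. VIM fell by 1.33, the squamous genes S100A9 and DSG1 rose by 1.51 and 1.84, and KRT13 fell by 1.79. Not called either were metallothioneins (1 and 3 of 7, 0.176), immediate early genes (3 and 8 of 24, 0.21), hypoxia (9 and 4 of 26, 0.323), basal keratinocyte genes (7 and 4 of 18, 0.442) and lipid uptake (6 and 7 of 22, 0.512). The same held for p53 targets (4 and 3 of 20, 0.591), histones (1 and 3 of 8, 0.649), NF-kB targets (9 and 6 of 23, 0.664), extracellular matrix (12 and 9 of 39, 0.859) and H3K4 methylation machinery (6 and 6 of 19, 0.921). Among the basal genes KRT15 fell by 1.78 and the lineage factor TP63 rose by 1.08.

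Markers of blood cells (2 higher of 5, adjusted p = 0.114), fibroblasts (3 higher and 2 lower of 8, 0.664) and Schwann cells and neurons (2 and 2 of 5, 0.859) were not called at 14 days, while 2 of 4 endothelial markers fell. With fry 9 lists not called by camera passed at 14 days. Those higher were blood (0.000268), squamous (0.00316), hypoxia (0.0196) and lipid uptake (0.0211) genes, and those lower neurotrophins (0.00124), metallothioneins (0.00316), mesenchymal transition (0.00553), histones (0.0318) and PPAR targets (0.0384). Median, mean and test differed in sign for the basal, extracellular matrix, fibroblast, H3K4 and Schwann cell lists. Adjusted over the list alone, 20 cholesterol genes, 15 fatty acid synthesis genes and 24 oxidative phosphorylation genes were lower and 11 adhesion genes higher. The counts of the other called lists at 14 days were as over all genes. None of the 12 lists called at 14 days kept the call with an estimated correlation. The adhesion call was also lost without PA replicate 1 (0.0542), PA replicate 2 (0.0536) or untreated replicate 3 (0.0792), with adjusted p from 0.0136 to 0.0792 over the settings at the preset correlation.

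**Figure D2:**
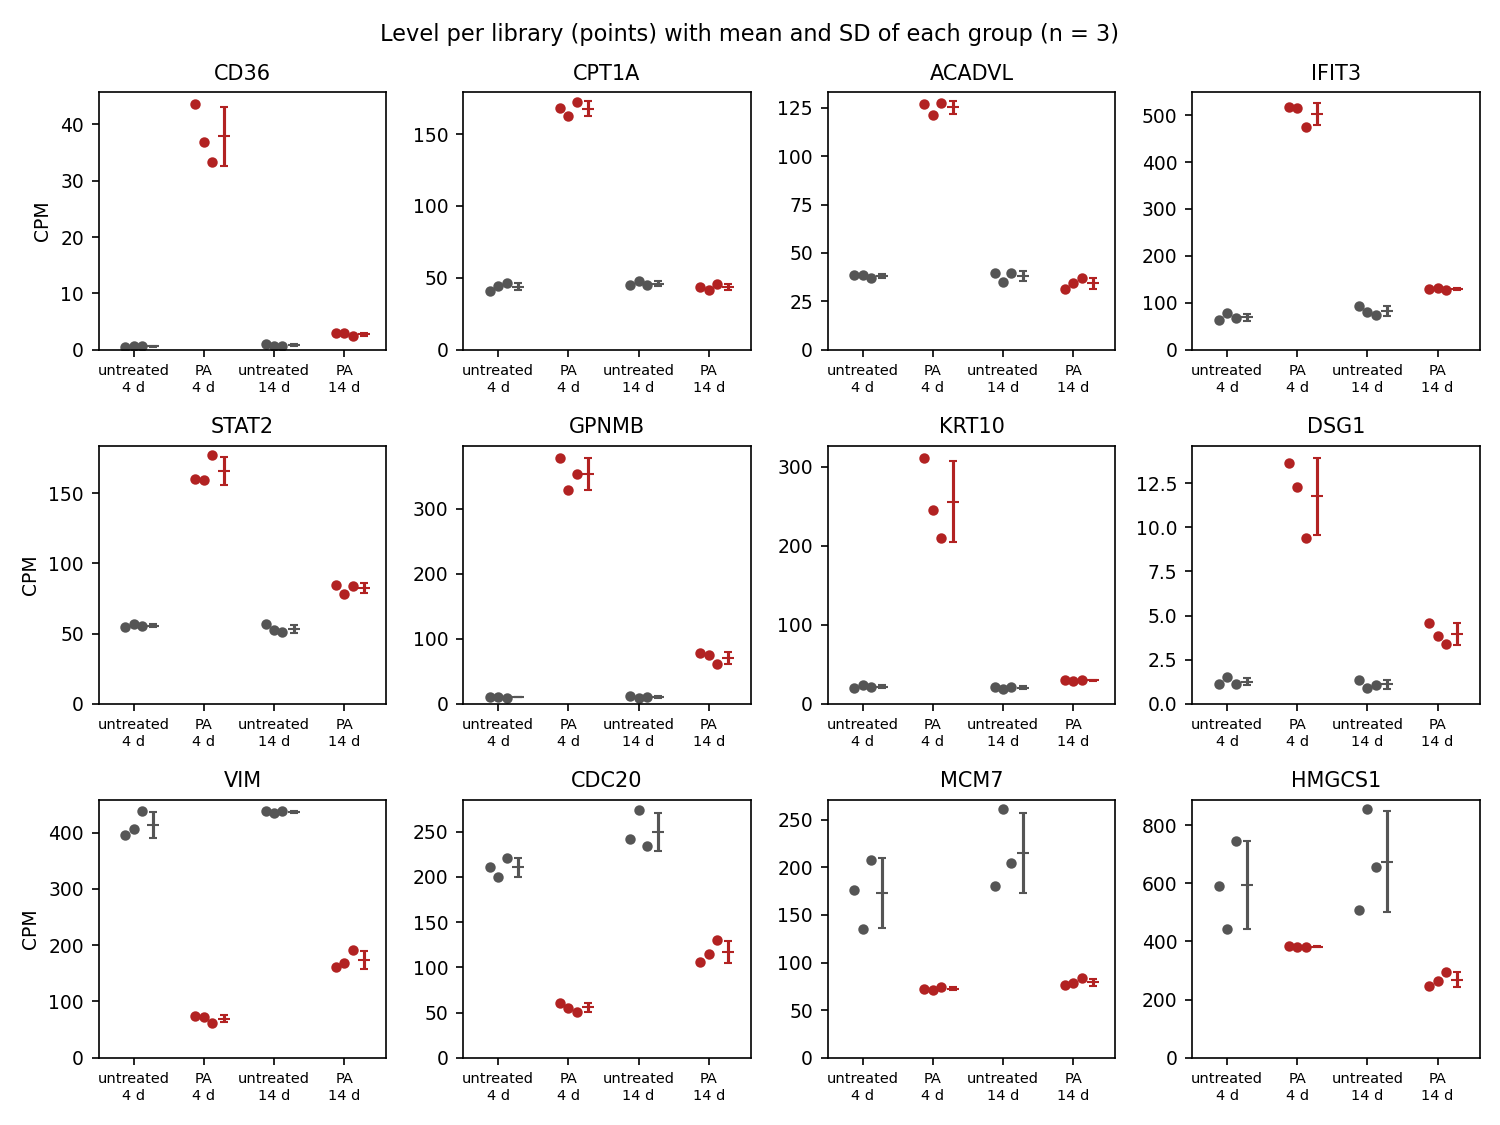
Levels of 12 genes in CPM (vertical axes, from 0) in each library of the 4 groups on the horizontal axes, as points (grey, untreated; red, PA), with the group mean and SD (n = 3) beside them. CPT1A rose from 44.0 to 168 CPM at 4 days and lay at 46.0 and 43.7 CPM at 14 days, while VIM was lower at both times.

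Whether the effect of PA differed between the times was tested directly, as the log2 fold change at 14 days minus that at 4 days. The interferon list rose less at 14 days than at 4 days, with 22 of 32 genes called, and the mitosis list fell less, with 12 of 27. Neither difference held with an estimated correlation (adjusted p = 0.172 and 0.504). The rise of fatty acid oxidation genes at 4 days was not seen at 14 days, and the sterol and glycolysis lists, not called at 4 days, were lower at 14 days. Of these lists, that of PPAR targets and fatty acid oxidation kept its difference with an estimated correlation (adjusted p = 0.0183). A difference in sorting or batch between the times that acted alike on PA and untreated libraries would cancel here. One that acted on them unequally would enter these values, and which applied is not stated. CD36 had a difference of −4.17, ACAA2 of −3.91 and ANGPTL4 of −3.20. KRT15 rose at 4 days and fell at 14 days, a difference of −3.51, and LINC00707 was lower at both times but less so at 14 days, a difference of 3.83.

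The difference passed the test for 7351 genes, 34.1% of those tested, with 3384 positive and 3967 negative, and it was at least 2-fold for 769 and 1202. With library totals alone the split was 4837 positive and 2992 negative, 61.8% positive against 46%. The negative end also held the apoptosis regulator BMF (−3.70), the xenobiotic oxidase CYP1A1 (−3.10), SERPINF1 (−3.08), KRT10 (−3.01), the coactivator of mitochondrial genes PPARGC1A (−3) and the mitochondrial carrier UCP2 (−2.86). The positive end held the matrix protease MMP3 (3.70), KRT34 (3.46), SMOC1 (3.22), SFTA1P (3.17), and UPP1 (3.17). It also held OSBP2 (2.79), MICAL2 (2.78), the cytokine gene IL1A (2.76) and PAPPA2 (2.74). Untreated libraries varied widely for some of these: UPP1 was at 256 ± 157 CPM in untreated cells at 14 days.

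Of 23 PPAR and fatty acid oxidation genes 17 had a negative difference and none a positive one (median −1.07, adjusted p = 2.5e-24, and 0.0183 with an estimated correlation), the one list whose call held with an estimated correlation. Interferon genes differed negatively for 22 of 32 (median −1.17, adjusted p = 5.47e-23, and 0.172 with an estimated correlation), IFIT2 by −2.64 and IFIT3 by −2.20. Of the genes higher at 4 days, 27 of 32 interferon genes were still called higher at 14 days against 1 of 17 PPAR and fatty acid oxidation genes, 2 lists compared after their values were seen and with different medians at 4 days (2.34 and 0.694). Mitosis genes differed positively for 12 of 27 (median 0.445, adjusted p = 0.000101) and cholesterol genes negatively for 16 of 24 (median −0.431, adjusted p = 0.000101), both with adjusted p = 0.504 at an estimated correlation.

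Negative differences were also called for hypoxia (3 positive, 13 negative of 26, median −0.45, adjusted p = 0.00094, and 0.172 with an estimated correlation), immediate early genes (4 and 14 of 24, −0.781, 0.00135, and 0.504), and lipid uptake (1 and 9 of 22, −0.273, 0.00135, and 0.0594). They were called, too, for extracellular matrix (7 and 20 of 39, −0.53, 0.00518, and 0.504) and glycolysis (2 and 12 of 19, −0.502, 0.00702, and 0.504). Further negative lists, in the same order of values, were mitochondrially encoded genes (0 and 7 of 13, −0.434, 0.0117, and 0.551), DNA replication (0 and 6 of 25, −0.509, 0.0117, and 0.653), and squamous differentiation (3 and 12 of 28, −0.347, 0.0128, and 0.243). The last of them were histones (1 and 5 of 8, −0.614, 0.0347, and 0.212) and adhesion genes (1 and 7 of 19, −0.261, 0.0443, and 0.504). Positive differences were called for epithelial-mesenchymal transition (17 and 8 of 35, 0.319, 0.00207, and 0.243), and metallothioneins (4 and 0 of 7, 0.639, 0.00214, and 0.172), and also for the unfolded protein response (9 and 1 of 22, 0.358, 0.00702, and 0.504) and NF-kB targets (10 and 2 of 23, 0.398, 0.0332, and 0.504). The ATF4 (4 and 1 of 27, adjusted p = 0.0773) and NRF2 (4 and 13 of 25, 0.0773) lists did not pass. ATF4 genes passed with the GC and length trend removed (0.0457), without untreated replicate 3 at 4 days (0.0236) and without untreated replicate 1 (0.00484) or 3 (0.0378) at 14 days, from 0.00484 to 0.281 over the settings at the preset correlation. NRF2 genes passed without PA replicate 3 (0.0493) or untreated replicate 3 (0.0236) at 4 days and without untreated replicate 1 at 14 days (0.0411), from 0.0236 to 0.15. Lists of fatty acid synthesis (3 and 7 of 24, 0.0925), neurotrophins (6 and 13 of 35, 0.123), fibroblast (0 and 4 of 8, 0.18) and Schwann cell and neuron markers (0 and 2 of 5, 0.254) were not called. Ribosomal proteins (2 and 9 of 45, 0.275), oxidative phosphorylation (1 and 4 of 32, 0.298), p53 targets (2 and 7 of 20, 0.316), basal keratinocyte genes (6 and 6 of 18, 0.321), blood markers (1 and 1 of 5, 0.631) and H3K4 machinery (1 and 3 of 19, 0.769) did not pass either, and for the basal list median, mean and test differed in sign. With fry negative differences passed for Schwann cell markers (0.00283), neurotrophins (0.00455), fatty acid synthesis (0.00478), p53 targets (0.00563), fibroblast markers (0.00874), NRF2 (0.0244) and basal genes (0.0396). Ribosomal genes passed without PA replicate 3 at 4 days (0.0223, from 0.0223 to 0.653). Of the 4 endothelial markers 1 differed negatively. Adjusted over the list alone, 24 interferon, 17 cholesterol, 15 glycolysis, 11 mitochondrially encoded, 9 adhesion and 2 DNA replication genes differed negatively. In the same way 14 genes of the unfolded protein response and 13 mitosis genes differed positively.

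The DNA replication difference was −0.284 and lost its call without untreated replicate 2 at 14 days (adjusted p = 0.091, from 0.000339 to 0.091 over the settings at the preset correlation), and fry did not call it (0.126). Relative to all untreated libraries, its genes lay at −0.966, −1.06 and −1.14 in PA libraries at 4 days and −1.17, −1.11 and −1.06 at 14 days. Untreated libraries lay at −0.182, −0.524 and 0.106 at 4 days and −0.065, 0.559 and 0.102 at 14 days. The difference thus lay mostly in the untreated libraries. The squamous, lipid uptake and adhesion medians were −0.23, −0.158 and −0.143 with library totals alone. The NF-kB median was 0.138 without untreated replicate 2 at 4 days (adjusted p = 0.0551) and 0.212 without untreated replicate 2 at 14 days. Its call was also lost without PA replicate 2 at 4 days (0.0582), without PA replicate 3 at 14 days (0.0725), with library totals alone (0.0897) or with the GC and length trend removed (0.0616), with adjusted p from 0.00818 to 0.0897 over the settings at the preset correlation, and fry did not call it (0.0511). The adhesion list lost its call without any one of 6 of the 12 libraries, with library totals alone (0.0695) and with the GC and length trend removed (0.24), with adjusted p from 0.0188 to 0.24 over the settings at the preset correlation.

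**Figure D3:**
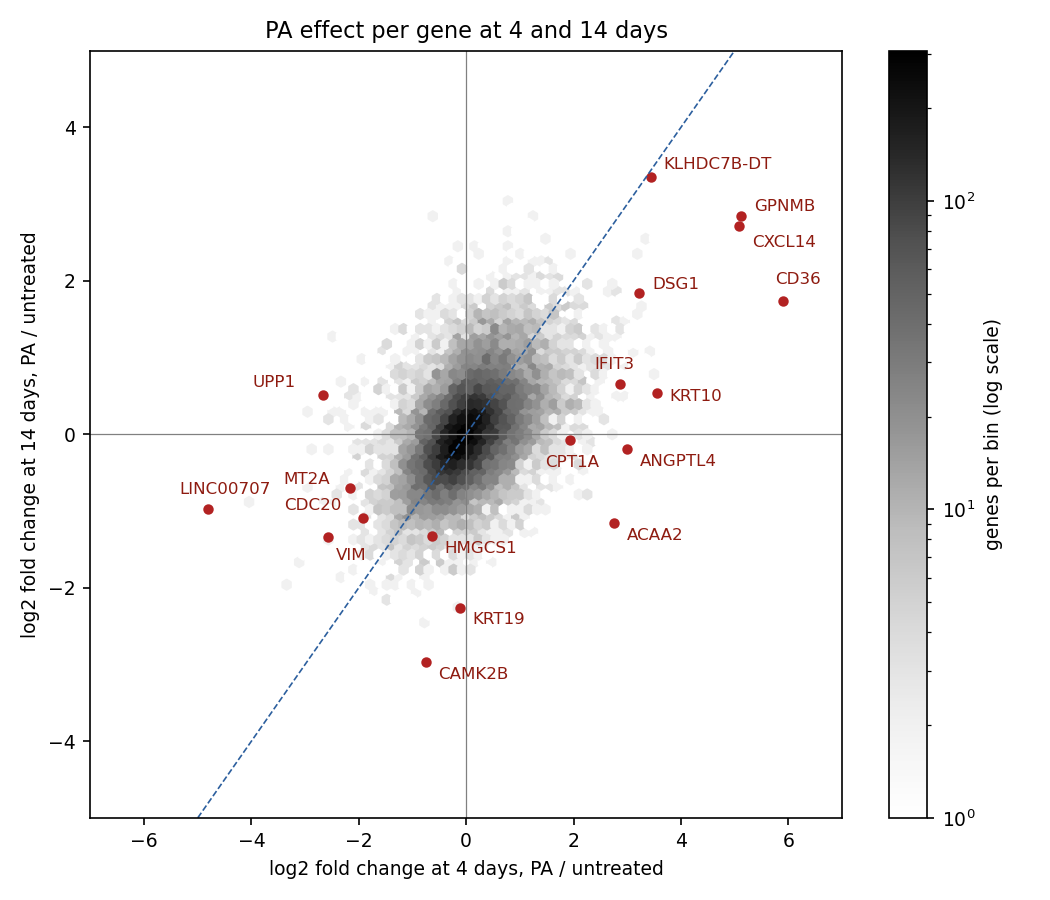
Log2 fold change of PA over untreated for the 21529 tested genes at 4 days (horizontal axis) and at 14 days (vertical axis), shaded by the number of genes per bin on a log scale, with named genes in red and a dashed line where both are equal. CD36 lay at 5.91 and 1.74, CPT1A at 1.93 and −0.08, and CAMK2B, at −2.97 on the vertical axis, among the genes with the deepest falls at 14 days.

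Genes that changed at both times were counted to ask how far the response at 4 days was seen again at 14 days, with no control library shared between the 2 comparisons. GPNMB, CXCL14, IFI44L, KLHDC7B-DT, DSG1 and CD36 rose at both times, and VIM, CDC20, MCM7, MT2A and LINC00707 fell at both. The shared calls numbered 2439 higher genes, where independent lists would give 1336.7 (odds ratio 3.78, Fisher's exact test over genes), and 3077 lower genes, where they would give 1454.3 (odds ratio 6.51). With library totals alone the balance turned, to 3107 higher and 2392 lower. Opposite calls were fewer, with 669 genes higher at 4 days and lower at 14 days and 398 the other way. The difference was called for all 1067 of them, which opposite calls largely imply, so that count is no separate evidence. Adjusted over the list of genes called at 4 days alone, 2492 of the higher and 3158 of the lower genes were called the same way at 14 days.

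Across the 21529 genes, which are not independent replicates, the log2 fold changes at the 2 times had a Pearson correlation of 0.459 and a Spearman correlation of 0.454. The Pearson correlation was 0.152 without the low-count filter and ran from 0.375 to 0.504 without one library. Among the 2682 genes called with at least 2-fold change at 4 days, 80.5% had the same sign at 14 days and 88.9% a smaller change, with a median absolute log2 fold change of 1.41 at 4 days and 0.668 at 14 days. A smaller value on the second measurement is partly given by choosing genes for a large first one. Of the 1694 genes that rose at least 2-fold at 4 days, 902 were called higher at 14 days, 705 were not called and 87 were lower. Of the 988 that fell, 563 were called lower, 379 not called and 46 higher.

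Untreated cells at 14 and 4 days were compared as the background between the times. CYP1A1, a target of the aryl hydrocarbon receptor, was higher at 14 days, at 16.1 ± 1.38 against 6.13 ± 0.125 CPM (SD, n = 3, adjusted p = 1.88e-06). In all 16 genes were higher and 0 lower by edgeR, with 3843 genes at an unadjusted p under 0.05, and DESeq2 called 392 higher and 86 lower. The 2 groups were fully separated for 20.1% of genes, where chance gives 10%. CAMK2B (1.14), ANO1-AS1 (1.12), KRT13 (0.98) and the histone gene H4C8 (0.80) were also called higher. Each lost its call when only the 6 untreated libraries were fitted (adjusted p = 0.402) and without untreated replicate 1 or 2 at 4 days, with 0.402 as the highest value over the settings. Between these groups 1 gene was called with the replicate block and 2 with the GC and length trend removed. CAMK2B and KRT13 were lower in PA than in untreated libraries at 14 days, and part of those falls may lie in the higher untreated level.

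Camera called 10 lists between the untreated groups, none of which held with an estimated correlation. DNA replication genes were higher at 14 days (median 0.403, adjusted p = 1.46e-12, and 0.783 with an estimated correlation), as were NRF2 genes (0.218, 9.17e-06, and 0.613), mitosis (0.135, 0.000703, and 0.898), histones (0.239, 0.00184, and 0.185), and glycolysis (0.192, 0.0031, and 0.871). Also higher were mitochondrially encoded genes (0.146, 0.0323, and 0.898), cholesterol genes (0.0733, 0.0439, and 0.898) and fibroblast markers (0.435, 0.0478, and 0.709). ATF4 genes (−0.484, 1.68e-08, and 0.783) and the unfolded protein response (−0.181, 2.75e-05, and 0.783) were lower. Relative to all untreated libraries, replicate 2 at 14 days lay apart from replicates 1 and 3, at 0.559 against −0.065 and 0.102 for DNA replication, at −1.16 against 0.2 and 0.0121 for ATF4 and at −0.222 against 0.0148 and −0.00937 for unfolded protein response genes. Median, mean and test differed in sign only in lists that were not called, those of basal, matrix, mesenchymal transition, H3K4, hypoxia, metallothionein, neurotrophin, p53 and PPAR genes. Of the members of all lists, 1 histone gene and 1 squamous differentiation gene, KRT13, were called on their own. Adjusted over the list alone, 4 histone and 5 NRF2 genes were higher and 5 genes of the unfolded protein response lower. The time, the state of sorting and any batch between the 2 sets of libraries could not be separated in this comparison.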

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

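Every result here was singled out because the PA effect at 14 days differed from that at 4 days in a direct test of the difference, and the tests on GC content and length and on library scaling were chosen only after the results were seen. The difference was positive for 3384 genes and negative for 3967, and 669 genes were called higher at 4 days and lower at 14 days and 398 the other way round. Among 50 drawn splits of the day labels within treatment, only 1, the real one, reached the 7351 called genes, and the highest other split gave 5582. That split and the next, with 5164, kept the PA libraries on their own days. The other drawn splits mixed the days of the PA libraries, which puts the day difference into the spread. Their low counts therefore carry little weight.

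Lists with a negative median difference were interferon response (−1.17), PPAR targets and fatty acid oxidation (−1.07), immediate early genes (−0.781), replication-dependent histones (−0.614), extracellular matrix (−0.53), DNA replication (−0.509), glycolysis (−0.502), hypoxia (−0.45), mitochondrially encoded genes (−0.434), cholesterol synthesis (−0.431), squamous differentiation (−0.347), lipid uptake (−0.273) and epithelial adhesion (−0.261). Positive medians were found for metallothioneins (0.639), mitosis (0.445), NF-kB and inflammatory cytokines (0.398), the unfolded protein response (0.358) and epithelial-mesenchymal transition (0.319). Of these 18 lists, PPAR targets and fatty acid oxidation kept the call with an estimated correlation. The DNA replication difference lay mostly in the untreated libraries, as PA libraries had similar levels at both times. Untreated medians also moved for the unfolded protein response (−0.181), histones (0.239), glycolysis (0.192), mitochondrially encoded (0.146) and cholesterol genes (0.0733). These shifts were opposite in sign to the differences, so part of each difference may lie in untreated libraries. The untreated mitosis median moved by 0.135, with the sign of its difference.

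The single genes were LINC00707 (3.83), MMP3 (3.7), KRT34 (3.46), SMOC1 (3.22), SFTA1P (3.17), UPP1 (3.17), OSBP2 (2.79), MICAL2 (2.78), IL1A (2.76) and PAPPA2 (2.74) with a positive difference. Those with a negative difference were CD36 (−4.17), ACAA2 (−3.91), BMF (−3.7), KRT15 (−3.51), ANGPTL4 (−3.2), CYP1A1 (−3.1), SERPINF1 (−3.08), KRT10 (−3.01), PPARGC1A (−3) and UCP2 (−2.86). None of the 20 lost the call under any alternative. Of 220 further named genes, 148 had a called difference.

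The calls in the PA comparisons were broad, 51.8% and 50% of the tested genes, a breadth that could come from GC content and length or from library scaling. With the GC and length trend removed, 11349 genes were called at 4 days and 11149 at 14 days, against 11162 and 10764 without. That trend thus does not account for the breadth. With library totals as the only scaling 11121 and 11238 were called. The TMM factors ran only from 0.957 to 1.07, so this change could hardly have lowered the count, and it does not decide on scaling. Whether any grouping of the libraries would do was examined with 10 splits of the 6 libraries per comparison, too few for a share under 0.05. In each, 1 split reached the real count, the real one itself. It gave 11068 genes at 4 days, 10133 at 14 days and 1 between the untreated groups, with 0 as the highest other in all. Every other split in a PA comparison mixed PA and untreated libraries, which puts the PA difference into the spread. Those counts of 0 therefore carry little weight. A biological reading, a broad effect of PA, remains, but a handling difference between PA and untreated cultures could not be tested with these libraries.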

How the results depend on the processing

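The counts of genes called in the PA comparisons, in their difference and at both times stayed within 1.5 times under every alternative but glmTreat, although library totals moved the balance of higher and lower genes at 14 days to 7234 and 4004. Changes of 1.2-fold were rarely recovered in simulated data, in which far fewer genes were changed. Library totals and the GC and length trend were tests chosen after the data were seen. Against 1.2-fold (glmTreat), 3653 genes were higher and 3372 lower at 4 days, 2656 and 2981 at 14 days, 1765 and 2479 for the difference, and 1 between untreated groups, a stricter test by construction. Between untreated groups 891 genes were higher and 657 lower without the low-count filter, 392 and 86 with DESeq2, and 1 gene was higher with only the libraries compared, 1 with a replicate block, 9 with library totals and 2 with the GC and length trend removed. The cause was not tested. With an estimated correlation 3 lists were called at 4 days, 0 at 14 days and 1 for the difference, and with fry 22, 21 and 23, with 1 between untreated groups. The cause was not tested, and fry asks a different question, whether a list changed at all. SETD1A at 4 days turned to −0.1556 with the GC and length trend removed (adjusted p = 0.0198), and the cause was not tested. Without one library, calls ranged over 4780 to 5243 higher and 5077 to 5307 lower at 4 days, 4169 to 5201 and 4860 to 5524 at 14 days, 2757 to 3599 and 3326 to 4195 for the difference, and 2 to 102 and 0 to 17 between untreated groups. Shared calls ranged over 2015 to 2431 and 2659 to 3128, and called lists over 11 to 14, 11 to 13 and 16 to 20. The replicate block gave 5315 higher and 5366 lower genes at 4 days, 4932 and 5178 at 14 days, and 3069 and 3538 for the difference, where the adhesion list lost its call (0.0752) and the ATF4 list gained one (0.0331), as did immediate early genes at 4 days (0.0213), while SCD at 4 days lost its call (0.0583). Correlations of replicates with the same number, 0.043, −0.039 and −0.095 at 4 days and 0.054, 0 and 0.045 at 14 days, do not pair the samples. Of the named genes, glmTreat kept 382 results and weakened 40, DESeq2 kept 419 and weakened 3, and leaving out a library kept 3248 and weakened 91. Fitting only the libraries compared does not apply to the difference, which uses all 12.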

Other observations

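The 6 gene groups described first were all chosen after values of their members were seen, and the 3 tests on ATF4 genes were chosen only after that result was seen, so their p-values are optimistic. Lysosomal genes of the CLEAR network, which encode hydrolases and membrane proteins of lysosomes, were higher in PA libraries at 4 days for 24 and lower for 1 of 26 (median log2 fold change 0.674, camera p = 1.05e-13, and adjusted p = 0.0108 over the 6 groups with an estimated correlation). The cathepsins CTSF and CTSD rose by 1.65 and 1.35 and the glucosidase GAA by 1.71, beside the lysosomal GPNMB at 5.12. At 14 days 10 were higher and 3 lower (median 0.0851, camera p = 0.0296, and adjusted p = 0.285 with an estimated correlation). The 5 tested apolipoprotein L genes rose at 4 days (median 2, adjusted p = 0.00132 with an estimated correlation), APOL1 by 2.84, and 3 were higher and 1 lower at 14 days (median 0.245, adjusted p = 0.25). Targets of the aryl hydrocarbon receptor were higher for 4 and lower for 2 of 7 at 4 days (median 0.505, adjusted p = 0.022 with an estimated correlation) and higher for 1 and lower for 4 at 14 days (median −0.171, adjusted p = 0.25), with CYP1A1 at 2.30 and −0.81. These targets were also higher in untreated cells at 14 than at 4 days (median 0.228, adjusted p = 0.00127 with an estimated correlation), with 2 of 7 called. The untreated level at 14 days had thus itself moved for some of them. That test partly restates CYP1A1, which was called between the untreated groups.

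Genes of HLA class I and peptide loading were higher for 11 of 12 at 4 days (median 1.1, adjusted p = 0.022 with an estimated correlation) and for all 12 at 14 days (median 0.581, adjusted p = 0.0522). HLA-B rose by 1.56 and 2.27 and B2M by 1.39 and 1.24, where reads of the similar HLA genes are uncertain. Complement genes were higher for 8 and lower for 1 of 11 at each time (medians 1.04 and 1.1, adjusted p = 0.022 and 0.0522 with an estimated correlation, so that neither HLA nor complement genes passed it at 14 days), with the protease C1S at 3.29 and 2.84 and factor B, CFB, at 2.65 and 2.50. Keratins of simple epithelia fell for 4 of 5 at 4 days and for all 5 at 14 days (medians −1.06 and −0.965, adjusted p = 0.00825 and 0.00513 with an estimated correlation), KRT18 by 1.06 and 0.96 and KRT8 by 0.50 and 1.11. In untreated cells they were higher as a group at 14 than at 4 days (median 0.244, adjusted p = 0.0225 with an estimated correlation), with 0 of 5 called singly.

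ATF4 stress response genes were higher in PA libraries at 14 days, which might come from a single library or from a low level in the untreated libraries. No library ended the call, as the highest adjusted p without one library was 5.48e-05, but without untreated replicate 2 the median was 0.397 instead of 0.848. Against the untreated libraries at 4 days the median of the PA libraries at 14 days was 0.325, with 3 genes called higher and 2 lower of 27. Relative to those libraries the untreated replicates at 14 days lay at −0.0369, −1.51 and −0.281 and the PA replicates at 0.36, 0.378 and 0.383. Much of the size went with a low level in untreated libraries, mostly in replicate 2. Whether the part that remained, a median of 0.397 without that replicate, was an effect of PA is left open.

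Pseudogenes (907 called at 4 days and 951 at 14 days) and antisense genes (901 and 879) were among the called genes, and reads of a parent or overlapping gene could account for them. Of called pseudogenes with a tested parent, 88.2% moved with the parent at 4 days and 84% at 14 days, where the highest of 1000 shuffled pairings gave 68.9% and 64.8%. Of called antisense genes with a tested sense gene (350 and 313), 81.4% and 82.7% moved with it, against 58.6% and 59.1%. VIM-AS1 fell by 2.22 and 1.37 beside VIM at −2.58 and −1.33, and KRT8P45 by 0.51 and 1.15 beside KRT8. Shared reads remain a candidate for many of these calls, and for antisense genes regulation together with the sense gene was not excluded.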
